A study of Homo sapiens with 12 samples.

How the data were processed

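A375 is an established human melanoma line. Per the labels' protocols, cells were plated overnight and exposed to ciclopirox, crizotinib or the vehicle DMSO for 8 h or 24 h, and 300 ng of total RNA was amplified and biotin-labelled for Illumina bead arrays. Groups came from the sample titles. The titles number the replicates and do not say that they were separate cultures. The limma p-values of genes therefore measure the spread between these arrays, which may be technical. All 12 arrays lay on 1 chip.

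The authors deposited a table with, per the file headers, an average signal intensity and a detection p-value for each of 47231 probes on each array. GenomeStudio is the processing tool named in the submitters' processing notes, with no version. The signals had already been background-subtracted, since 28.8% were below 0. A second deposited table, named by sample, held the authors' normalized intensity of 38220 of these probes, on a linear scale from 12.0 to 38205.3. Its columns had nearly equal distributions, with medians from 28.3 to 29.6, and the normalization method is not given in the sources used here. Because of that, a change in the total RNA level of a group cannot be seen in these values.

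The 2 tables conflicted. Each column of the second table was set against every scanner column over probes detected on all arrays. Each followed 1 scanner column closely (r from 0.928 to 0.980, next best at most 0.841), but only the 2 controls followed the column named in their own description. The design fixed beforehand used background-corrected, quantile normalized scanner signals (neqc, offset 16) with the columns named by the descriptions, and allowed the second table on a log2 scale if it alone could be used. The scanner signals could be used, so that condition was not met to the letter. The second table nevertheless became the main analysis after the conflict had been seen, when 12 of the 12 arrays were found nearest to an array of their own group under the second table's names and 7 of 12 under the descriptions. This was a choice informed by the data. A fit on the planned signals and names is given beside the main counts. It used the detection filter and the probe choice of the main analysis, described below. The planned test was therefore not run in full. In further alternatives each scanner column was given to the sample whose values it followed, which assigns columns by their values, and no main result rests on that step. On the chip, groups lay in blocks under either naming, so position and group cannot be told apart.

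A second departure followed from the first. The planned filter, detection on every array of a group, needs named scanner columns, so probes with a detection p-value under 0.01 on at least 2 of the 12 arrays were kept instead, 16563 in all. A value was called above background on an array when it exceeded the 99th percentile of the 20196 probes detected on no array. This call matched the detection p of the corresponding scanner column in 97.3% of cases, over all 38220 probes. These include the 20196 that set the threshold, 99% of which match by construction, so the share among the other probes is lower. Where a gene was above background in 1 group only, the change is a bound, from the bright group's mean against the higher of the dim value and the lowest value above background. List medians and list tests use the fitted values of all members, also of those near background. Of the value table's probes, 27002 had 1 gene symbol, 4 had several and 11214 were unnamed here, from the platform annotation. By gene number, 26968 named probes were found in the reference table, and 0 symbols changed. A single probe per gene was used, that with the highest mean, which left 10330 genes. Other probes of a gene went the opposite way for SYVN1 and EGFR at 8 h of ciclopirox, ANGPTL4 and EGFR at 8 h of crizotinib, and SDHC, KDM2B and (by -0.051) MYC at 24 h of crizotinib.

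Log2 values were fitted in R 4.3.3 with limma 3.58.1, a mean per group over all 12 arrays and empirical Bayes moderation (7 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment within each of 9 comparisons and calls at an adjusted p under 0.05. The 24 gene lists, of 650 genes, were fixed before the data were examined, and 492 members were measured. The 22 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated one. At the preset correlation the camera p-values take genes as the units, so they do not measure the spread between arrays. The estimated setting also uses the 7 residual degrees of freedom of the arrays. With the estimated correlation, 10 of the 26 list calls against control were lost, and these are listed with the dependence on processing. The keratinocyte and leukocyte lists had 4 and 3 measured genes and were not tested. TFRC and several other fixed genes are not analysed here.

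Genes were named by a rule fixed beforehand. For each comparison against control it took the 8 largest rises and 8 largest falls among called genes above background on all arrays of both groups and with arrays that did not overlap. It added up to 2 bounds per direction, up to 3 called members per list and a set of 12 genes that included VEGFA, MYC, MET and CDKN1A. For the time and drug comparisons it took 5 each way, and for the difference of time changes 4. Other list members given as examples, such as ATF5 and SREBF1 at 24 h, were in part chosen after their values were seen. On data simulated for the 10330 genes, the test recovered 30% to 44% of genes changed by 0.5 on the log2 scale, 88% to 93% at 1 and 98% to 100% at 2, over the comparisons against control. Only 50 or 100 genes were changed at each size, with independent noise. Far more genes were called in the real comparisons, so these rates may not hold there. Unchanged groups against shared controls were simulated 100 times. Alternatives covered the source of the signals, background correction, scaling, the detection filter, probe averaging, the variance model, array weights, the samples in the fit, a replicate block and leaving out each array. Plots were drawn with matplotlib.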

Results

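Gene expression was measured in the human melanoma cell line A375 after treatment with ciclopirox, an antifungal agent that chelates iron, or crizotinib, an inhibitor of the receptor tyrosine kinases MET and ALK. Cells received each drug at its 75% inhibitory concentration, which had been determined at 72 h. The 12 arrays fell into 5 groups, with 2 vehicle controls, 3 arrays of ciclopirox at 8 h, 2 of ciclopirox at 24 h, 3 of crizotinib at 8 h and 2 of crizotinib at 24 h. The study was set up to derive an expression signature of each drug and to relate it to the outcome of patients with melanoma, and patient data were not analysed here. The labels give no time for the control arrays, so the same 2 arrays served both times.

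The deposited scanner columns and the deposited value table named different samples. The values of each array in the value table followed 1 scanner column (correlation of deviations 0.928 to 0.9801), but for 10 of the 12 arrays that was not the column given in the sample's description. All values below use the names of the value table, a choice made after this conflict had been seen. The scanner signals planned beforehand, named by the descriptions, were fitted with the main analysis's detection filter and probes, not with the planned filter. That fit called 0 genes in 7 of the 9 comparisons. It called 215 for ciclopirox at 8 h against control and 2164 for crizotinib against ciclopirox at 8 h. Of 347 calls of the genes chosen by rule, 4 were kept under those names, 250 were lost and 93 turned in direction. Of the 93, only SESN1 at 8 h of ciclopirox was itself called under those names (1.73, limma adjusted p = 0.0435). By their values, the columns described as ciclopirox 8 h were the value table's crizotinib 24 h replicates 1 and 2 and ciclopirox 24 h replicate 1. Under the descriptions' names the p53 and mitotic lists had medians of 1.07 and -0.71 at 8 h of ciclopirox. Of 26 list calls against control, 4 were kept, those of p53 targets, ATF4, DNA replication and heat shock genes at 24 h of ciclopirox. A further 13 were lost and 9 turned in direction. Interferon response and ribosome biogenesis genes passed in the turned direction at 8 h of ciclopirox and 24 h of crizotinib. Lysosome genes did so at 8 h of ciclopirox. Most calls below therefore depend on the value table's names being right. Limma tested 10330 genes, and precision was limited by the 2 or 3 arrays per group.

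**Figure D1:**
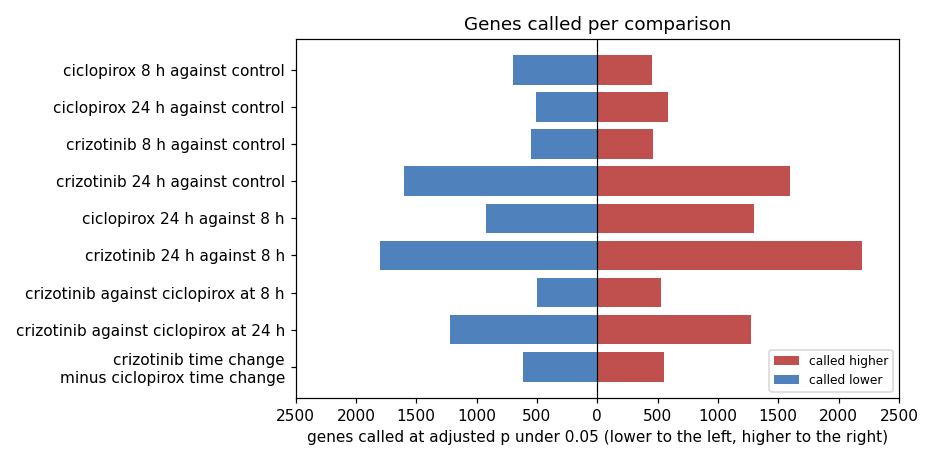
Bars give the number of genes called at an adjusted p under 0.05 in each comparison, lower to the left and higher to the right. Crizotinib at 24 h against control had 1599 genes higher and 1605 lower, and ciclopirox at 24 h had 587 higher and 510 lower.

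The first comparison asked which genes 8 h of ciclopirox altered. Genes known to be induced by the hypoxia-inducible factors rose together. Of 23 measured HIF target genes, 14 rose and none fell (16 when adjusted over the list alone), with a median log2 change of 0.58 (camera adjusted p = 1.55e-14). With an estimated correlation the list's camera adjusted p was 0.00222. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 1.66 ± 0.15 (SE, n = 3 against 2, limma adjusted p = 0.000375) on the probe used, while its other probe changed by 0.12. HK2, which catalyses the first step of glycolysis, rose by 1.44 ± 0.10 (0.88 on its other probe) and VEGFA, an angiogenic growth factor, by 0.80 ± 0.12. The mitophagy receptors BNIP3 and BNIP3L rose by 1.01 and 0.85. NDRG1, another HIF target, did not pass the test (-0.14, adjusted p = 0.38). Ribosome biogenesis genes also rose, 7 of 30 with none lower (8 adjusted over the list alone), with a median of 0.20 (adjusted p = 2.71e-06).

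Other large rises at 8 h of ciclopirox were ADAMTS6 (1.59), SPRY1 (1.52, with 0.97 on its other probe), a feedback inhibitor of growth factor signalling, VLDLR (1.48) and EDN1 (1.29). MYC rose by 0.89. The largest falls were CEMIP (-1.84 ± 0.13), a hyaluronan-degrading protein, DKK3 (-1.48), TNFRSF19 (-1.47), PRRX1 (-1.42, with -0.63 on another probe) and the hyaluronan synthase HAS3 (-1.35). Among interferon response genes 8 of 27 fell and none rose, including IFIT1, which was at least 2.05-fold lower and not above background on the treated arrays. That list had a median of -0.23, and its call was lost with an estimated correlation (adjusted p = 0.153). The melanocyte lineage regulator SOX10 fell by 0.59 on the log2 scale, while MITF (0.09, adjusted p = 0.83) did not pass. In total 454 genes were called higher and 697 lower. Leaving out any 1 array of these 2 groups reduced the 1151 calls, to between 268 (without control replicate 1) and 702 (without ciclopirox 8 h replicate 1), and scanner signals matched to the value table and scaled to the median gave 184 higher and 1526 lower.

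At 24 h of ciclopirox, p53 target genes and genes of the ATF4 amino acid response rose. Of 21 measured p53 targets, 18 rose and none fell (20 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 3.98e-20). GDF15, a stress-induced cytokine, was at least 10.98-fold higher and SESN2, which restrains mTORC1, at least 4.39-fold higher, neither being above background on the control arrays. The ATF4 list also holds SESN2. MDM2, the ubiquitin ligase of p53, was at least 2.34-fold higher. In the ATF4 list 19 of 28 genes rose and 1 fell (22 higher and 2 lower adjusted over the list alone), with a median of 0.65 (adjusted p = 8.07e-19). ATF3 rose by 2.18 ± 0.16 (SE, n = 2 against 2, limma adjusted p = 5.49e-05), CTH, an enzyme of cysteine synthesis, by 2.06 ± 0.19, DDIT3 by 1.97 ± 0.16 and PCK2 by 1.74 ± 0.16. The transcription factor ATF5 was the member that fell (-0.55).

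HIF targets were again higher at 24 h of ciclopirox, with 12 of 23 called and a median of 0.39 (adjusted p = 3.67e-10), among them DDIT4 (1.49), STC2 (1.26), VEGFA (1.08) and ANGPTL4 (1.42, with 0.16 on its other probe). Glycolysis enzymes rose with a median of 0.28, led by ALDOC (1.40) and ENO2 (1.10). Outputs of the MAPK pathway rose in 11 of 23 genes, including EGR1 (1.83) and FOS (1.48). DUSP6, of the same list, was not called (0.08, with 0.66 on its other probe). Mitotic genes fell, 22 of 39 with none higher (30 adjusted over the list alone) and a median of -0.52 (adjusted p = 2.26e-18), including ASPM (-0.98) and BUB1 (-0.95). DNA replication genes had a median of -0.27 with 14 of 38 lower, a call lost with an estimated correlation (adjusted p = 0.104). Heat shock genes fell in 9 of 16 with a median of -0.48. HSPA1A (-2.82 ± 0.17) and HSPA1B (-1.67 ± 0.11) had the largest falls of all genes ranked, but they are near-identical copies whose probes may not separate them. RPPH1 (-1.37) and SNORD3D (-1.17), small RNAs without a poly(A) tail, were also lower. In total 587 genes were higher and 510 lower. A limma fit on only the ciclopirox 24 h and control arrays called 103 higher and 45 lower. The 1097 calls fell to between 337 (without ciclopirox 24 h replicate 2) and 701 (without ciclopirox 24 h replicate 1) when an array of these 2 groups was left out, and median-scaled matched scanner signals gave 340 higher and 520 lower.

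**Figure D2:**
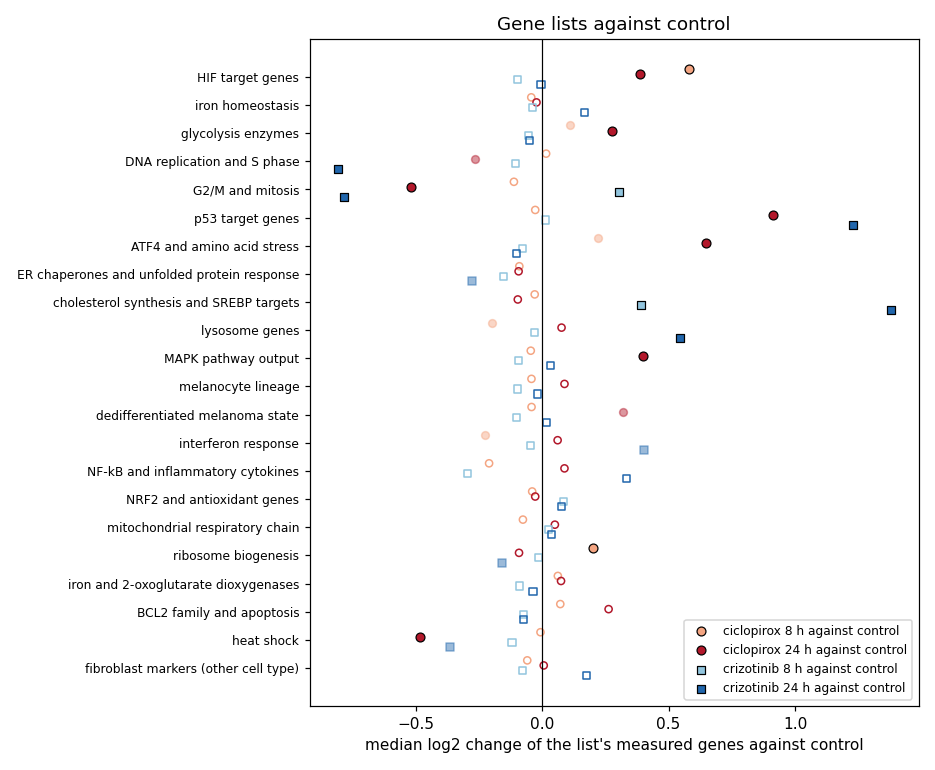
Each point is the median log2 change against control of 1 gene list, for ciclopirox (circles) and crizotinib (squares) at 8 h (light) and 24 h (dark). Open points did not pass the camera test, faded points passed with the preset correlation, and outlined points passed with an estimated correlation too. The cholesterol synthesis list lies at 0.39 and 1.38 for crizotinib, and the HIF target list at 0.58 and 0.39 for ciclopirox.

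After 8 h of crizotinib, genes of cholesterol synthesis rose. Of 23 measured members 13 rose and 1 fell (14 higher and 1 lower adjusted over the list alone), with a median log2 change of 0.39 (camera adjusted p = 2.63e-07). INSIG1, a sterol-regulated inhibitor of SREBP processing, rose by 1.73 ± 0.09 (SE, n = 3 against 2, limma adjusted p = 1.3e-05) on the probe used and 1.10 on its other probe, HMGCS1, which makes the precursor of mevalonate, by 1.64 ± 0.08 and MSMO1, a sterol oxidase, by 1.18 ± 0.11. Mitotic genes were higher, 14 of 39 with none lower (22 adjusted over the list alone) and a median of 0.30 (adjusted p = 2.1e-11), including AURKB (0.65) and MKI67 (0.66). The cytokine IL24 rose by 1.84, the cyclin CCNA1 by 1.77, TXNIP by 1.51 and the cell cycle inhibitor CDKN1B by 1.15, with 0.26 on its other probe.

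The largest falls at 8 h of crizotinib were the chemokine CXCL8 (-2.00 ± 0.12), HAS3 (-1.82), PMEPA1 (-1.77), CEMIP (-1.55), the EGFR ligand TGFA (-1.46), EDN1 (-1.38) and HES1 (-1.36). The cytokines IL1A (-1.17) and IL1B (-1.09) also fell. DUSP6, a phosphatase induced by ERK activity, fell by 0.57 on the log2 scale (-0.28 on another probe) and CCND1 by 0.36, whereas MET itself did not pass (-0.27, adjusted p = 0.18). The MAPK output list, which holds DUSP6 and CCND1, did not pass at 8 h of crizotinib (6 of 23 lower, 2 higher, median -0.09, adjusted p = 0.531) or at 24 h (2 lower, 7 higher, median 0.03, adjusted p = 0.517). HIF targets had a median of -0.10 and did not pass as a list (adjusted p = 0.531). In total 460 genes were higher and 552 lower. The 1012 calls fell to between 216 (without control replicate 1) and 869 (without crizotinib 8 h replicate 3) when an array of these 2 groups was left out, and median-scaled matched scanner signals gave 182 higher and 1506 lower.

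At 24 h of crizotinib the cholesterol synthesis genes stood higher still, with 19 of 23 raised, 1 lowered and a median of 1.38 (camera adjusted p = 7.4e-15). HMGCS1 rose by 3.82 ± 0.09 (SE, n = 2 against 2, limma adjusted p = 4.68e-09), a 14.1-fold change, MSMO1 by 3.39 ± 0.12 and INSIG1 by 2.84 ± 0.10. The exception, SREBF1, a transcription factor of lipid synthesis, fell by 0.83 on the log2 scale. IL24 rose by 4.23 ± 0.12. Of 21 p53 targets 20 rose and none fell, with a median of 1.23 (adjusted p = 2.13e-16). GDF15 was at least 12.4-fold higher and the cell cycle inhibitor CDKN1A at least 5.88-fold higher, while TP53INP1 rose by 2.47 ± 0.19. Lysosome genes rose in 17 of 28 with 1 lower and a median of 0.55 (adjusted p = 3.21e-08), including GPNMB (1.88) and the protease CTSF (1.79).

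Genes of cell division fell at 24 h of crizotinib. DNA replication genes were lower in 36 of 38, with a median of -0.81 (adjusted p = 1.01e-21), including E2F2 (-1.78), POLE2 (-1.67) and MCM10 (-1.63). Mitotic genes were lower in 35 of 39, with a median of -0.78 (adjusted p = 2.16e-20), including SPC25 (-1.44), CDK1 (-1.34) and CCNA2 (-1.17). Other large falls were the protease inhibitor SERPINA3 (-2.85 ± 0.26), XYLT1 (-1.98), CNIH2 (-1.97, with -0.86 on another probe) and the collagen COL8A1 (-1.85, with -1.18 on another probe). The ER chaperone HSPA5 fell by 1.28 on the log2 scale. Interferon response genes had a median of 0.40, with 13 of 27 higher and 2 lower, and lost their call with an estimated correlation (adjusted p = 0.0845). Markers of other cell types moved too, with CD68, which is also a lysosomal protein, at 1.13, and the fibroblast markers LUM and MFAP5 at 1.002 and 1.005, while the fibroblast marker COL6A3 fell (-0.56) and the fibroblast list did not pass (adjusted p = 0.293). In total 1599 genes were higher and 1605 lower. The 3204 calls fell to 2033 without crizotinib 24 h replicate 1 and to 2104 without control replicate 1, and median-scaled matched scanner signals gave 821 higher and 3013 lower.

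**Figure D3:**
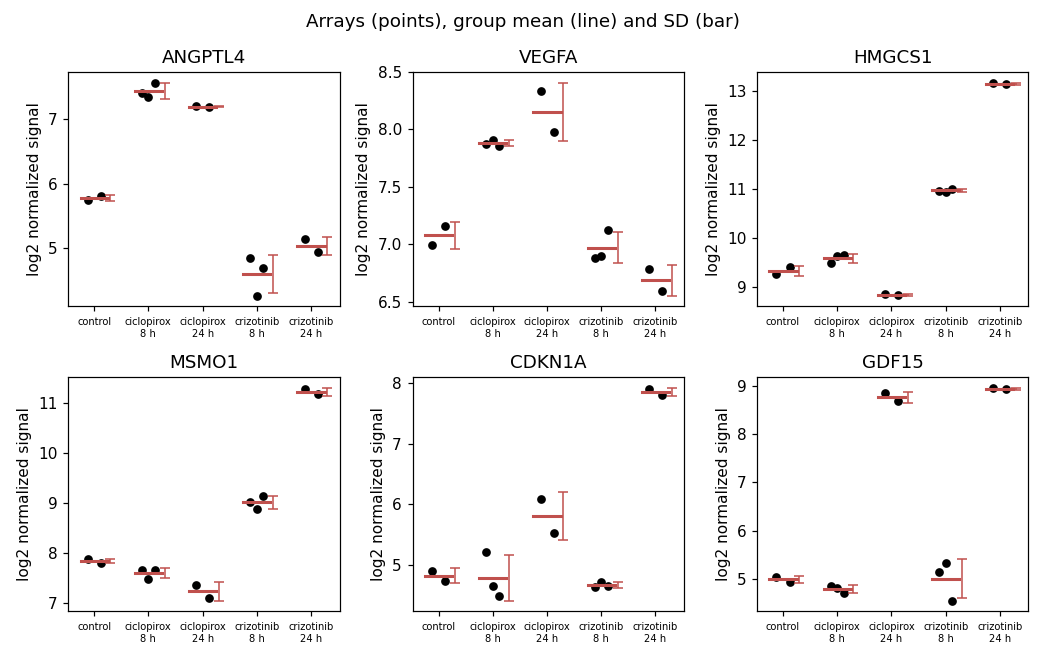
Points are single arrays, lines group means and bars the SD, on the log2 scale of the normalized signal, for 6 genes in the 5 groups. HMGCS1 and MSMO1 are highest on the crizotinib 24 h arrays, VEGFA is higher on every ciclopirox array than on any other, and GDF15 is high in both 24 h groups.

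Between 8 h and 24 h of ciclopirox, a comparison that uses no control array, p53 targets rose by a median of 1.02 (20 of 21 higher, adjusted p = 6.65e-16) and ATF4 genes by 0.61 (20 of 28 higher, 1 lower, adjusted p = 3.34e-10). Mitotic genes fell by a median of 0.42 on the log2 scale (25 of 39 lower) and ribosome biogenesis genes by 0.31 (13 of 30 lower). The largest rises were CEMIP (2.31), EGR1 (2.16), BLOC1S2 (1.88), IL1A (1.87) and FOS (1.83), and the falls included MIX23 (-1.36) and PCLO (-1.26). In total 1299 genes were higher and 924 lower, and median-scaled matched scanner signals gave 1555 and 454. The count was 1222 without ciclopirox 24 h replicate 1 and 1283 without ciclopirox 24 h replicate 2.

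The same interval of crizotinib lowered 38 of 39 mitotic genes (median -1.10, adjusted p = 9.95e-27) and 36 of 38 DNA replication genes (median -0.76). It raised 20 of 21 p53 targets (median 1.25), 19 of 23 cholesterol genes (median 1.002) and 20 of 28 lysosome genes (median 0.41, 1 lower). SUGCT (2.98), the smooth muscle actin ACTA2 (2.88), IL1B (2.65) and SESN1 (2.57) rose most, and MIX23 (-2.17), FANCB (-1.97, with -1.08 on its other probe) and HAUS8 (-1.89) fell most. In total 2191 genes were higher and 1797 lower, and 2558 were called without crizotinib 24 h replicate 1. Median-scaled matched scanner signals gave 1682 higher and 2033 lower, which turned the majority.

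The drugs were then compared directly. At 8 h, HIF targets were lower with crizotinib than with ciclopirox in 16 of 23 genes and higher in none (median -0.61, adjusted p = 2.57e-20). Mitotic genes were higher with crizotinib in 25 of 39 (median 0.42) and cholesterol genes in 12 of 23 (median 0.37). EDN1 differed most (-2.67 ± 0.14, limma adjusted p = 3.54e-06), having risen with ciclopirox and fallen with crizotinib, followed by CCN2 (-1.62) and CXCL8 (-1.54) on the lower side and IL24 (2.26) and INSIG1 (1.67) on the higher. In total 532 genes were higher with crizotinib and 503 lower, and the count fell to 503 without ciclopirox 8 h replicate 3, the lowest of the 6 left-out arrays, and to at most 707 without ciclopirox 8 h replicate 1. Median-scaled matched scanner signals gave 356 higher and 362 lower.

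At 24 h, ATF4 genes were lower with crizotinib in 22 of 28 (median -0.83, adjusted p = 1.89e-16) and cholesterol genes higher in 19 of 23, with 1 lower (median 1.48, adjusted p = 2.15e-16). DNA replication genes were lower in 31 of 38 (median -0.56), p53 targets higher in 12 of 21 with 1 lower (median 0.44), and HIF targets lower in 11 of 23 with 3 higher (median -0.37). HMGCS1 was 19.8-fold higher with crizotinib (log2 4.30 ± 0.09), while SERPINA3 (-3.01), the glycine transporter SLC6A9 (-2.59) and EGR1 (-2.13) were lower. In total 1275 genes were higher and 1219 lower, against 716 and 1999 for median-scaled matched scanner signals. The count was 1379 without crizotinib 24 h replicate 1 and 1511 without ciclopirox 24 h replicate 2.

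The change from 8 h to 24 h differed between the drugs for 1172 genes, 554 with a more positive change under crizotinib and 618 with a more negative one. HMGCS1 (2.92), MSMO1 (2.58), DHCR7 (2.44) and BHLHE40 (2.04) led the first set, and SERPINA3 (-3.28), SLC6A9 (-2.26), EGR1 (-2.21) and FOS (-1.86) the second. The count fell to 583 without crizotinib 24 h replicate 1, 634 without ciclopirox 24 h replicate 2 and 775 without crizotinib 24 h replicate 2, and median-scaled matched scanner signals gave 292 and 857.

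The drugs shared called genes. At 8 h, 143 genes were higher and 249 lower with both, and 9 went opposite ways, where independent lists would share 20.2 and 37.2 and oppose in 55.3. At 24 h, 302 were higher and 323 lower with both and 67 opposite, against 90.9, 79.2 and 170 for independent lists. Simulated unchanged groups against the same controls shared 0 to 0.01 genes on average. Unchanged groups have almost no called genes to share, so this count is no baseline for the overlap of the real lists. Across genes, which are not independent replicates, the log2 changes correlated at 0.58 at 8 h and 0.44 at 24 h, against 0.60 and 0.50 in the simulation, and the covariances were 0.0488 and 0.0666 against 0.0134 and 0.0135. Within a drug, the 8 h and 24 h changes correlated at 0.37 for ciclopirox and 0.28 for crizotinib, below the 0.55 of the simulation for each, and the covariances were 0.0342 and 0.0374 against 0.0134 and 0.0135. Within ciclopirox, 121 genes were higher and 110 lower at both times and 35 opposite, against 25.8, 34.4 and 62.0 for independent lists. Within crizotinib the numbers were 174, 225 and 114, against 71.2, 85.8 and 157. The 2 controls could not be split with 2 arrays in each part, so part of these overlaps may come from the shared controls.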

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

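The comparison of time changes was set beforehand. The tests that weigh explanations were picked for that use after their results had been seen, although those on detection, on 24 h against 8 h and on the drugs at 24 h rest on comparisons or alternatives set beforehand. The change from 8 h to 24 h differed between the drugs for the lists and genes that follow, by a test of the difference itself in camera or limma, given as crizotinib minus ciclopirox on the log2 scale.

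The cholesterol synthesis list differed by a median of 1.04, the ATF4 list by -0.62, mitotic genes by -0.67 and DNA replication genes by -0.46, and these 4 lists passed with an estimated correlation too (largest adjusted p = 0.0490). The other lists passed with the preset correlation only. These were p53 targets (0.28, adjusted p = 0.0586 with an estimated correlation), HIF targets (0.23, adjusted p = 0.128), iron homeostasis (0.31, adjusted p = 0.333), lysosome genes (0.14, adjusted p = 0.152), the dedifferentiated melanoma state (-0.18, adjusted p = 0.103), the mitochondrial respiratory chain (-0.15, adjusted p = 0.114) and heat shock (0.15, adjusted p = 0.153). The change was more positive with crizotinib for HMGCS1 (2.92), MSMO1 (2.58), DHCR7 (2.44), BHLHE40 (2.04), HSPA1A (1.56), SUGCT (1.52), AHNAK2 (1.29), HSPA1B (1.09), ACTA2 (1.06), SESN1 (0.87) and IL1B (0.84). It was more negative for SERPINA3 (-3.28), SLC6A9 (-2.26), EGR1 (-2.21), FOS (-1.86), FANCB (-1.56), HAUS8 (-1.45), SPC25 (-1.15), BLOC1S2 (-1.05) and CEMIP (-0.89). A difference does not tell which drug moved a gene. EGR1 and FOS rose with ciclopirox (2.16 and 1.83) and changed by -0.05 and -0.03 with crizotinib. HSPA1A fell with both drugs, by more with ciclopirox (-2.07) than with crizotinib (-0.51). SERPINA3 rose with ciclopirox (1.51) and fell with crizotinib (-1.77). Under the descriptions' names this comparison called 0 genes in limma (1521 at an unadjusted p under 0.05).

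The scanner columns and the value table named different samples. By the descriptions 7 of 12 arrays had their nearest array in their own group and under the value table's names all did, 12 of 12, which argues against single arrays exchanged in the value table and is consistent with descriptions that name the wrong columns. This closeness had also informed the choice of the value table, so it is no independent support for it, and it would survive an exchange of whole groups of equal size. Iron chelation is known to raise HIF target genes. On the HIF target list the lowest ciclopirox array lay 0.44 above the highest other array, which argues against exchanged drug names. The rise of that list is itself a result of these arrays, and the test was chosen after it was seen. The iron homeostasis list did not set the ciclopirox arrays apart. Its highest medians were on the crizotinib 24 h arrays (0.197 and 0.148). Exchanged columns of 8 h and 24 h of a drug, or of control and crizotinib 8 h, would join groups of 3 and 2 arrays. An array would then lie outside its group, which the 12 of 12 argue against. An exchange of control with crizotinib at 24 h, 2 arrays each, stays open, although both controls followed the column of their own description. Titles that give whole groups the wrong time would leave the 12 of 12 unchanged, so these stay open, and no biological explanation was tested.

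Crizotinib at 24 h had more calls against control than ciclopirox at 24 h. Among genes detected on all 12 arrays the ratio of the counts was 2.38, which argues against detection as the whole cause. With matched scanner signals scaled to the median it was 4.46, where the main counts were 3204 and 1097. Crizotinib thus had more calls under either processing. The scaling moved the median of all genes by -0.19 at 24 h of crizotinib and by -0.05 at 24 h of ciclopirox. It may itself enlarge the ratio, so this ratio cannot tell how much the normalization contributes. That scaling moved the share of higher calls at 24 h of crizotinib from 49.9% to 21.4%, so the split by direction stays open. Each drug was given at its own 75% inhibitory concentration, and a biological difference between the drugs or their doses stays open, as untested.

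At 24 h p53 targets rose and mitotic genes fell with both drugs. Against the 8 h arrays, which uses no control, the list medians were at least 0.82 times those against control, which argues against chance values of the 2 controls. Both lists also differed between the drugs at 24 h (largest adjusted p = 0.0360 with an estimated correlation), which argues against time in culture as the whole cause. The labels give the controls no time, so the part common to both drugs may still reflect time in culture, and a drug response stays open beside it.

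For crizotinib against ciclopirox at 8 h, fitted on those 6 arrays alone, the real grouping called 747 genes and the others at most 0. The 6 arrays make 10 splits, 1 of which called that many, and 10 are too few for a share under 0.05.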

How the results depend on the processing

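The 4 settings chosen after seeing the data were scanner signals matched to the value table by their values, with neqc, without background correction or scaled to the median, and a further quantile normalization of the value table. Background and scaling alternatives set beforehand were not run on columns named by the descriptions, and the matched ones stand in their place. The planned signals and names, neqc on scanner columns named by the descriptions, were fitted with the main detection filter and probes. This fit called 215 genes in limma for ciclopirox at 8 h against control and 2164 for crizotinib against ciclopirox at 8 h. It called 0 in each of the other 7 comparisons, where 660 to 2376 genes had an unadjusted p under 0.05. Of the 215, 32 were among the main calls, 25 in the same direction, and of the 2164, 238 were, 80 in the same direction. The same signals with matched columns called 1258 to 4295 genes, all within 1.5 times the main counts, so the loss comes from which column is given to which sample. That does not show which naming is right, because matching by values makes the signals resemble the value table. Without a detection filter, with more genes tested, the counts were 461, 379 and 310 for ciclopirox at 8 h, ciclopirox at 24 h and crizotinib at 8 h against control, 1242 for ciclopirox 24 h against 8 h, 481 and 1662 for the drug comparisons at 8 h and 24 h, and 541 for the difference of time changes. For the same 3 comparisons against control a mean-variance trend with robust estimation gave 1748, 1699 and 1717, and fitting only the groups compared, with fewer arrays, gave 733, 148 and 251 and, for the drugs at 24 h, 1463. Array weights gave 724 for ciclopirox at 24 h. Matched signals scaled to the median gave 1688 for crizotinib at 8 h and moved the median of all genes by -0.12 (ciclopirox 8 h against control), -0.12 (crizotinib 8 h against control), -0.19 (crizotinib 24 h against control), -0.15 (crizotinib against ciclopirox at 24 h), -0.14 (the difference of time changes). Where no construction is named, the cause was not tested. Leaving out 1 array of the groups compared gave 268 to 702 for ciclopirox 8 h against control, 337 to 701 for ciclopirox 24 h against control, 216 to 869 for crizotinib 8 h against control, 2033 to 2304 for crizotinib 24 h against control, 1222 to 1659 for ciclopirox 24 h against 8 h, 503 to 707 for crizotinib against ciclopirox at 8 h, 583 to 1120 for the difference of time changes, 1379 to 1944 for crizotinib against ciclopirox at 24 h, 2558 to 3744 for crizotinib 24 h against 8 h. A lone array left in a group was assumed to vary like the other groups. With the replicate number as a block the counts ran from 688 (crizotinib at 8 h) to 3629 (crizotinib 24 h against 8 h), all within 1.5 times the main ones. Same-numbered arrays did not deviate together (21 pairs, r from -0.097 to 0.080), and 3 of 12 arrays correlated best with an array of their own number. Genes near background could be given as bounds only.

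Camera with an estimated correlation ended 10 of 26 list calls against control. Their medians, unchanged by that setting, and adjusted p were glycolysis 0.11 (adjusted p = 0.199, ciclopirox 8 h), ATF4 0.22 (adjusted p = 0.153, ciclopirox 8 h), lysosome -0.20 (adjusted p = 0.199, ciclopirox 8 h), interferon response -0.23 (adjusted p = 0.153, ciclopirox 8 h), DNA replication -0.27 (adjusted p = 0.104, ciclopirox 24 h), dedifferentiated state 0.32 (adjusted p = 0.0573, ciclopirox 24 h), ER chaperones -0.28 (adjusted p = 0.101, crizotinib 24 h), interferon response 0.40 (adjusted p = 0.0845, crizotinib 24 h), ribosome biogenesis -0.16 (adjusted p = 0.0913, crizotinib 24 h), heat shock -0.36 (adjusted p = 0.0913, crizotinib 24 h). Lists that passed only under another setting had these medians. With matched neqc they were at ciclopirox 8 h BCL2 family 0.13, at ciclopirox 24 h NF-kB 0.17, BCL2 family 0.21. With matched signals without background correction they were at ciclopirox 8 h BCL2 family 0.11, at ciclopirox 24 h NF-kB 0.11, BCL2 family 0.16. With matched signals scaled to the median they were at ciclopirox 8 h BCL2 family 0.011, at ciclopirox 24 h cholesterol synthesis -0.21, NF-kB 0.16, BCL2 family 0.19, at crizotinib 8 h ER chaperones -0.24. With no detection filter they were at ciclopirox 8 h mitosis -0.11, at ciclopirox 24 h NF-kB 0.12, BCL2 family 0.23, at crizotinib 8 h DNA replication -0.11, ER chaperones -0.17, at crizotinib 24 h iron homeostasis 0.17. With detection on all 12 arrays they were at ciclopirox 8 h melanocyte lineage -0.31, at ciclopirox 24 h BCL2 family 0.26. With the mean of all probes they were at ciclopirox 8 h BCL2 family 0.16, at ciclopirox 24 h BCL2 family 0.30. Leaving out 1 array changed a list call for glycolysis at ciclopirox 8 h (lost without control replicate 1, medians 0.11 to 0.20 over the arrays left out), lysosome at ciclopirox 8 h (lost without control replicate 1, medians -0.24 to -0.18 over the arrays left out), BCL2 family at ciclopirox 8 h (gained without control replicate 2 and ciclopirox 8 h replicate 2 and ciclopirox 8 h replicate 3, medians 0.014 to 0.16 over the arrays left out), BCL2 family at ciclopirox 24 h (gained without control replicate 2 and ciclopirox 24 h replicate 1, medians 0.15 to 0.26 over the arrays left out), ER chaperones at crizotinib 8 h (gained without control replicate 2, medians -0.21 to -0.14 over the arrays left out). Of 299 calls of named genes that use the controls, 102 were lost without control replicate 1 and 98 without control replicate 2, and 0 reversed. Without 1 array of a treated group, 9 to 27 of the 97 to 112 calls compared were lost. Of all 347, 92 were lost with only the groups compared, 79 without a detection filter, 38 with median scaling, 34 with the replicate block, 14 with the mean of all probes, and 5 to 12 with matched neqc, matched signals without background correction, a further quantile normalization, the variance trend or array weights. Of the 321 left with detection on all 12 arrays, 2 were lost. ANGPTL4 at 8 h of crizotinib turned to 0.13 when detection on all 12 arrays was required, and SYVN1 at 8 h of ciclopirox to 0.0090 and SDHC at 24 h of crizotinib to -0.084 with the mean of all probes, since other probes enter.

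Under the descriptions' names list medians moved as follows. By their values, the columns described as ciclopirox 8 h were the value table's crizotinib 24 h replicates 1 and 2 and ciclopirox 24 h replicate 1. Those described as ciclopirox 24 h were ciclopirox 24 h replicate 2 and crizotinib 8 h replicate 1. Those of crizotinib 8 h were crizotinib 8 h replicates 2 and 3 and ciclopirox 8 h replicate 1. Those of crizotinib 24 h were ciclopirox 8 h replicates 2 and 3. A cause beyond this assignment was not tested. Of 26 list calls against control, 4 were kept, at ciclopirox 24 h DNA replication -0.20, p53 targets 0.40, ATF4 0.31 and heat shock -0.31. Lost calls had medians at ciclopirox 8 h HIF targets 0.17, glycolysis 0.015, ATF4 0.16, at ciclopirox 24 h HIF targets 0.24, glycolysis 0.16, mitosis -0.15, MAPK output 0.21, dedifferentiated state 0.019, at crizotinib 8 h mitosis 0.16, cholesterol synthesis 0.26, at crizotinib 24 h mitosis -0.093, ER chaperones -0.11, heat shock 0.0034. Gained calls had medians at ciclopirox 8 h DNA replication -0.58, mitosis -0.71, p53 targets 1.07, ER chaperones -0.21, cholesterol synthesis 0.82, MAPK output 0.15, heat shock -0.38, at crizotinib 24 h HIF targets 0.56. Lists that turned in direction had medians at ciclopirox 8 h lysosome 0.35, interferon response 0.23, ribosome biogenesis -0.14, at crizotinib 24 h DNA replication 0.051, p53 targets -0.095, cholesterol synthesis -0.098, lysosome -0.19, interferon response -0.20, ribosome biogenesis 0.22. At ciclopirox 8 h lysosome (camera adjusted p = 6.60e-06), interferon response (adjusted p = 0.0218) and ribosome biogenesis (adjusted p = 0.0367) passed in the turned direction. At crizotinib 24 h interferon response (camera adjusted p = 0.00253) and ribosome biogenesis (adjusted p = 2.66e-06) did so, and the other turned lists did not pass. Of 347 calls of named genes, 4 were kept, 250 lost and 93 turned in direction under those names. A turn is a change of sign of any size, and of the 93 only SESN1 at 8 h of ciclopirox passed (limma adjusted p = 0.0435). The log2 changes that turned were at ciclopirox 8 h ANGPTL4 -0.12, EDN1 -0.91, ANKRD1 -0.29, CEMIP 0.060, SPSB2 0.038, SNORD57 -0.37, SLC39A14 -0.0098, E2F1 -0.087, GINS4 -0.35, SESN1 1.73, CCNG1 0.48, SYVN1 0.20, NAGLU 0.25, PSAP 0.56, SOX10 0.10, CCN2 -0.94, GBP2 0.057, IL1A 0.997, IL1B 1.40, AKR1C3 0.32, DDX21 -0.13, EGLN1 -0.033, KDM2B -0.36, at ciclopirox 24 h MSMO1 0.27, HMGCS1 0.57, SCD 0.11, at crizotinib 24 h IL24 -0.45, MSMO1 -0.19, AHNAK2 -0.15, INSIG1 -0.0079, ACTA2 -0.65, TP53INP1 -0.095, SUGCT -0.39, XYLT1 0.11, HAUS8 0.34, FANCB 0.19, GDF15 -0.27, CDKN1A -0.44, SNORD30 0.50, ADM 0.47, FTL -0.042, CYBRD1 -0.31, CCNA2 0.052, HYOU1 0.14, CTSF -0.18, NEU1 -0.21, CDK2 0.14, CCN2 0.88, ISG20 -0.54, IFIT2 -0.76, TAP1 -0.29, IL1B -0.32, IL1A -0.70, ABCC2 -0.51, CYCS 0.42, NDUFS7 -0.35, DKC1 0.36, NOP56 0.19, MRTO4 0.32, KDM5B -0.19, KDM2B 0.31, HSPE1 0.25, JUP -0.050, PERP -0.26, LUM -0.034, COL6A3 0.033, CD68 -0.092, CD14 -0.25, NDRG1 -0.15, MKI67 0.36, at ciclopirox 24 h against 8 h CEMIP -0.70, IL1A -0.91, HSPA1B 0.16, MIX23 1.36, PCLO 0.80, NEXN 0.37, at crizotinib 24 h against 8 h ACTA2 -0.33, AHNAK2 -0.23, HAUS8 0.12, at crizotinib against ciclopirox at 8 h IL24 -1.99, INSIG1 -0.59, LPIN1 -0.83, MSMO1 -1.39, HMGCS1 -1.23, EDN1 0.51, CCN2 0.66, ADAMTS6 0.24, XYLT1 0.74, at crizotinib against ciclopirox at 24 h HMGCS1 -0.32, MSMO1 -0.46, INSIG1 -0.63, IL24 -1.84, DHCR7 -0.0039.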

Other observations

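Several lists not described so far differed between the drugs. Genes of the NRF2 antioxidant response were higher with crizotinib than with ciclopirox at 8 h (4 of 22 higher, none lower, median 0.14, camera adjusted p = 0.00188) and at 24 h (9 higher, 1 lower, median 0.25, adjusted p = 0.0160), and both calls held with an estimated correlation (adjusted p = 0.0304 and 0.0491). The BCL2 family list was lower with crizotinib at 8 h (3 of 16 lower, 1 higher, median -0.18, adjusted p = 0.00280, and 0.0493 with an estimated correlation). The lower members were BNIP3 (-1.04) and BNIP3L (-0.66), which the HIF target list also holds, and PMAIP1 (-0.61), and BCL2 was higher (0.39). Against control the BCL2 family median was 0.26 at 24 h of ciclopirox (adjusted p = 0.0541) and -0.07 at 24 h of crizotinib (adjusted p = 0.987). With a member near background given as a bound, the median at 24 h of ciclopirox was 0.15. The pro-apoptotic members HRK and BAX rose at 24 h with ciclopirox (0.97 and 0.91) and with crizotinib (1.87 and 1.42, the latter with 0.78 on its other probe). At 24 h of crizotinib BNIP3L also rose (0.40), and BIRC2 (-0.77), PMAIP1 (-0.46), BID (-0.40) and BCL2 (-0.34) fell. AKR1C2, an aldo-keto reductase of the NRF2 list, fell at 8 h with ciclopirox (-1.20) and crizotinib (-0.82). CCN2, a connective tissue growth factor, rose at 8 h of ciclopirox (0.86) and fell with crizotinib at 8 h (-0.76) and 24 h (-1.60). TXNIP, which binds thioredoxin, rose at 24 h of ciclopirox (1.98). IL1B was higher than control at 24 h with ciclopirox (1.31) and crizotinib (1.56).

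The iron homeostasis list had medians of -0.04 and -0.02 at 8 h and 24 h of ciclopirox (adjusted p = 0.992 and 0.991), with 14 of 22 fixed members measured, and 1 gene called higher at 8 h. The iron and 2-oxoglutarate dioxygenases had medians of 0.06 and 0.07 (adjusted p = 0.358 and 0.155), the melanocyte lineage list -0.04 and 0.09 (adjusted p = 0.210 and 0.515), the NF-kB list -0.21 and 0.09 (adjusted p = 0.366 and 0.0755), the mitochondrial respiratory chain -0.08 and 0.05 (adjusted p = 0.366 and 0.170) and the fibroblast markers -0.06 and 0.01 (adjusted p = 0.973 and 0.938), so none passed. With crizotinib at 24 h, 3 of the 4 measured keratinocyte markers and 2 of the 3 leukocyte markers were called higher (medians 0.52 and 0.73), and neither list was tested. Their medians were 0.24 and 0.32 at 24 h of ciclopirox.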
